A study of Schistosoma mansoni with 8 samples.

How the data were processed

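Total RNA of adult Schistosoma mansoni worms was measured on 8 two-colour Agilent oligonucleotide arrays with probes 60 bases long. Per the labels, 4 biological samples of curcumin-treated worms were each hybridised against 1 of 4 samples of vehicle-treated worms, and each such pair was hybridised on 2 arrays with the dyes exchanged. RNA was extracted with Trizol, treated with DNase, linearly amplified and labelled with Cy3 or Cy5, per the labels' protocols. The 2 arrays of a pair hold the same 2 extracts and were counted as 1 replicate, which gave n = 4 pairs.

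Agilent Feature Extraction, named in the submitters' processing notes and given as version 9.5.3.1 in the file headers, produced the deposited scanner files. Their spot and background intensity values are linear, not normalized between arrays, and were deposited for each channel with marks for spots well above background, saturated spots and non-uniform outliers. These marks are coded values of another kind (1 or 0), as deposited. The log10 ratio of Cy5 over Cy3 in the same files is background-subtracted and dye-normalized, per the file headers. The deposited series table holds log2 ratios of curcumin over DMSO formed from the same processed signals. All 8 of its columns lay within 1e-06 of the log2 ratio recomputed from the scanner files, with rows matched by their order, which settled scale and direction. Its columns were not centred further. The medians over all spots were 0.098, 0.036, 0.194 and 0.072 for pairs 1, 2, 3 and 4 with curcumin in Cy3, and 0.001, -0.022, 0.125 and -0.009 with curcumin in Cy5.

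Each array held 43426 spots, of which 1417 were controls, and 41739 distinct worm probes with 40965 distinct sequences. The files repeat the probe's own name in the fields for gene and transcript: 0 probes had another gene name, 0 had a description, and 0 of their names occurred in the RefSeq gene table of assembly ASM23792v2, which lists 13257 genes and no sequences. The comparison was therefore made on probes. The 24 gene lists, the count of changed genes and the part of the naming rule that needs a gene name, all fixed before the data were examined, were not run. The naming rule took the largest changes among probes that passed the threshold with the same direction in all 4 pairs, and was held to the 2 largest rises and the 2 largest falls.

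From the mean and background intensities, the background was corrected with normexp (offset 50) and each array was normalized by loess in limma 3.58.1 under R 4.3.3. Control spots had weight 0, outlier spots were left out, and spots of 1 probe were averaged. Every ratio was turned to curcumin over DMSO from the dyes in the labels, and the dye-swapped arrays of a pair were averaged. A probe was tested if it was well above background on at least 4 of 8 arrays in the channel of either treatment and had at least 3 complete pairs. The filter kept 17018 probes, and 16710 had enough pairs. The mean over pairs was tested against 0 with limma (lmFit and eBayes, two-sided) at a Benjamini-Hochberg adjusted p under 0.05. Levels per treatment are log2 intensities of separate channels after loess and Aquantile normalization, averaged over the 2 dyes of an extract.

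The pairing comes from the hybridisation of both extracts on the same arrays. Deviations of same-numbered curcumin and DMSO extracts from their group means correlated across probes at 0.26, 0.37, 0.27 and 0.37 for pairs 1 to 4. The highest correlation of each curcumin extract with a DMSO extract of another number was 0.19, 0.38, 0.07 and 0.14, so that of pair 2 was not above the others. Both levels of a pair come from the same arrays, whose shared variation alone can raise same-numbered correlations. These values therefore cannot check the pairing of the worms. Each pair had its own slide and scan, so slide is already the block. Curcumin in Cy3 was always at one position of the slide and curcumin in Cy5 at another, so dye orientation and position cannot be told apart. The labels do not say whether the 4 pairs came from separate groups of hamsters.

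The procedure was tested on simulated data: arrays were drawn for 16319 probes, each on its own, with 200 probes changed. The spread was that between real pairs with that between real dye swaps added. Since the spread between pairs already holds dye-swap noise, the simulated spread was wider than the real one. It called 4% of 50 probes changed by 0.5 on the log2 scale, 64% of 100 changed by 1 and 98% of 50 changed by 2, and 5 of 16119 unchanged probes. Real probes can move together within an extract or array, so the simulated false calls do not cover shared effects. Real data with more changed probes have a less strict adjusted threshold. The number of arrays limits the precision.

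Sequence classes of probes were set from the open reading frames of the 60 bases. Composition and motif classes were fixed after the files had been read and before any ratio was computed. They were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry. A pair of probes was called overlapping if both shared a run of at least 25 bases on the same strand or on opposite strands. The 25 alternatives covered background, normalization, filters, flags, saturation, the deposited ratios, dye orientation, the model, the pairing, each pair left out, the threshold, overlapping probes and GC content, and 5 of them were chosen after the data had been seen.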

Results

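Gene expression was measured in adult worms of the blood fluke Schistosoma mansoni after exposure to curcumin, the yellow polyphenol of turmeric. The worms came from hamsters 56 days after infection and were held in culture for 24 h with 15 µM curcumin or with dimethyl sulfoxide (DMSO), the vehicle. The series comprised 4 curcumin extracts and 4 DMSO extracts, compared as 4 pairs on 8 arrays. Between 33.8% and 40% of the probes were well above background in the channel of the curcumin RNA, against 35.4% to 45.8% in the channel of the DMSO RNA. The observed log ratios of spiked-in control RNAs followed the expected ones with slopes of 0.883 to 0.924 per array. For 5 sequences printed at least 60 times per array, the log2 ratio varied between spots of 1 array with a median SD of 0.065.

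The 2 dye-swapped arrays of a pair gave log2 ratios that correlated across the tested probes at 0.87 in pair 1, 0.89 in pair 2, 0.69 in pair 3 and 0.79 in pair 4. Probes are not independent replicates, so these values describe only the likeness of the arrays. Averaged over the dye swap, pairs 2 and 4 were most alike, at 0.74, followed by pairs 1 and 2 at 0.66 and pairs 1 and 3 at 0.58. Pairs 1 and 4, 2 and 3, and 3 and 4 correlated at 0.38, 0.36 and 0.35. The array of pair 3 with curcumin in Cy5 stood apart, with correlations as low as 0.07 and 0.09 with arrays of pairs 4 and 2.

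**Figure D1:**
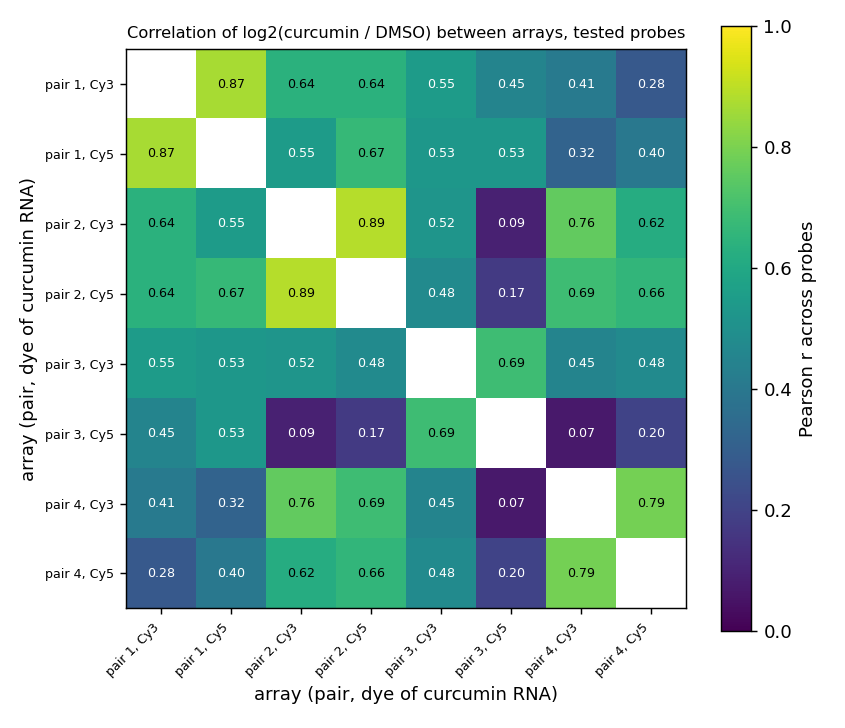
Pearson correlation across tested probes of log2(curcumin / DMSO) between the 8 arrays, each named by its pair and by the dye that carried the curcumin RNA; cells are coloured from 0 to 1. Arrays of the same pair correlate at 0.69 to 0.89, and the array of pair 3 with curcumin in Cy5 has the lowest values, down to 0.07.

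The comparison of curcumin with vehicle asked which transcripts of the adult worm change within 24 h of exposure. Of 16710 tested probes, 1023 were higher and 1272 lower with curcumin (limma, adjusted p under 0.05), 13.7% of those tested. All 2295 changed the same way in every pair in which they were measured, and 2230 were measured in all 4. With so few pairs the threshold nearly requires such agreement, and 4732 probes not past the threshold had it too. Most changes were small: the median ratio was 1.48-fold among the risen probes and 1.56-fold among the fallen ones. Among probes past the threshold, 112 rose and 185 fell at least 2-fold, and 16 rose and 3 fell at least 4-fold. The SD of the log2 ratio between pairs had a median of 0.22 over the tested probes. At an unadjusted p under 0.05 there were 5468 probes, where 836 would be expected by chance, but at an adjusted p under 0.01 only 1 probe was higher and 0 were lower. That probe rose by 2.16 on the log2 scale with a standard error of 0.09 (limma, adjusted p = 0.0052).

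The number of changed probes depended on the pairs. It was 2033 without pair 3, 456 without pair 4, 372 without pair 1 and 0 without pair 2 (limma; 3791 probes had an unadjusted p under 0.05 there). With the extracts unpaired, 130 probes were higher and 125 lower. Median centring over all probes in place of loess put the median of the tested probes at -0.209 on the log2 scale, and 85 probes were then higher and 868 lower. Relative to that shift, with the median of the tested probes as the centre, 1052 were higher and 1377 lower. That centre draws rises and falls toward balance by construction. Whether the shift was technical or an overall fall stays open, so the balance of directions depends on the chosen centre.

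**Figure D2:**
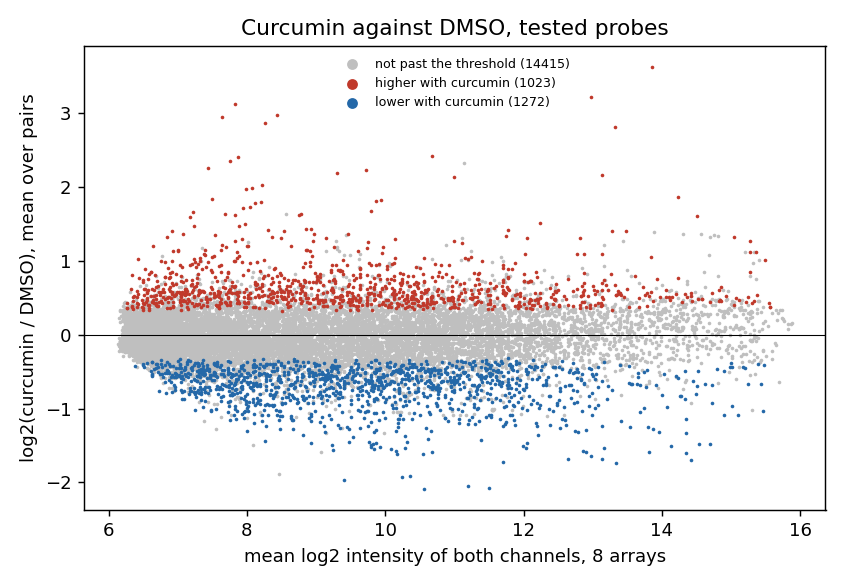
Mean log2(curcumin / DMSO) over the pairs (vertical) against mean log2 intensity of both channels over 8 arrays (horizontal), one point per tested probe. Red points are the 1023 probes higher with curcumin, blue points the 1272 lower ones and grey points those not past the threshold; called probes become sparse at the dim end.

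The probe with the largest measured rise past the threshold was Q2_P18655, with the sequence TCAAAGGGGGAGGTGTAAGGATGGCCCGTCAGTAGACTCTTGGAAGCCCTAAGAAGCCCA. The curcumin channel was saturated on 5 of 8 arrays, so its measured ratio is a lower limit there and its rank is open. With saturated spots at their recorded values, its log2 ratio was 3.62 ± 1.00 (SD, n = 4), a measured rise of 12.3-fold (limma, adjusted p = 0.013), with pair values of 4.45, 4.09, 2.19 and 3.73. Its level was 15.66 ± 0.56 (SD, n = 4) with curcumin and 12.04 ± 0.60 (SD, n = 4) with DMSO. None of its 3 sense reading frames was free of stop codons.

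The next largest measured rise was that of Q2_P07014, with the sequence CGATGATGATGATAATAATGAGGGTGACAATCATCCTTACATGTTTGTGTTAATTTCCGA. The curcumin channel was saturated on 1 of 8 arrays, where the ratio is a lower limit. The measured rise was 9.28-fold, 3.21 ± 1.5 on the log2 scale (SD, n = 4; limma, adjusted p = 0.022). Pair values ran from 1.85 in pair 3 to 5.12 in pair 4, so the size of this rise was less certain than its direction. Its single open sense frame reads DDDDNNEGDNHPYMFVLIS.

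Among the falls, Q2_P12526 had a log2 ratio of -2.08 ± 0.75 (SD, n = 4), a 4.24-fold fall (limma, adjusted p = 0.014). Its pair values were -1.17, -1.80, -2.87 and -2.49, and its level was 9.55 ± 0.28 (SD, n = 4) with curcumin against 11.63 ± 1.03 (SD, n = 4) with DMSO. The sequence of this probe is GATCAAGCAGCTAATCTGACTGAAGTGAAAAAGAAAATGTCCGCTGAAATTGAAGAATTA, whose single open sense frame reads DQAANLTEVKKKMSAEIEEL. Q2_P00621, with the sequence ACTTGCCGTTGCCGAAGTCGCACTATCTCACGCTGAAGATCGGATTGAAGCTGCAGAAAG, fell 4.23-fold, with a log2 ratio of -2.08 ± 1.06 (SD, n = 4; limma, adjusted p = 0.027). Its pair values of -3.21, -1.66, -2.65 and -0.80 differed more than those of Q2_P12526. The 95% confidence intervals of the 2 falls, -2.75 to -1.41 and -3.01 to -1.15, overlapped. Without pair 2, none of these 4 probes passed the threshold (limma, adjusted p of 0.073 to 0.097). Their direction could not change there, since the naming rule required the same direction in all 4 pairs.

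**Figure D3:**
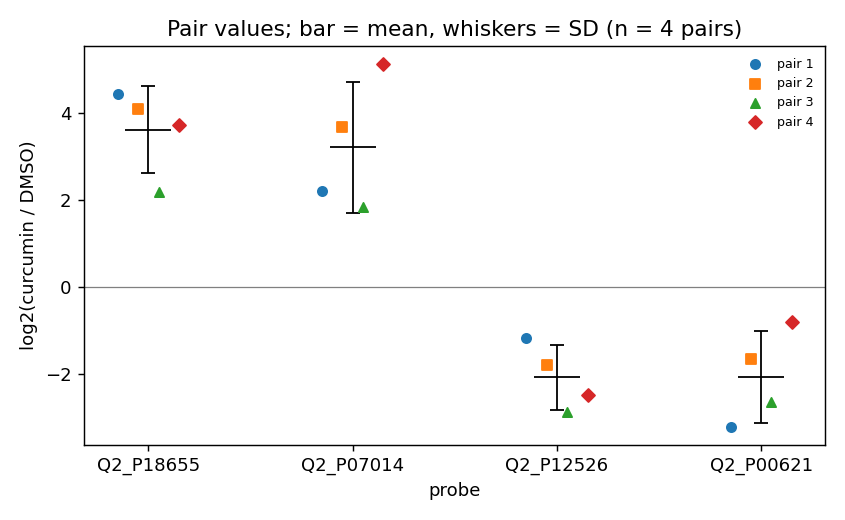
log2(curcumin / DMSO) of the 4 named probes in each of the 4 pairs (symbols), with the mean as a bar and the SD as whiskers. All pair values of Q2_P18655 and Q2_P07014 lie above 0 and all those of Q2_P12526 and Q2_P00621 lie below 0.

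Another 14 risen probes were not well above background in the DMSO channel on any array, and 2 fallen probes were not in the curcumin channel. For these only a bound can be given, against the lowest signal called well above background. The bounds of the 14 rises ran from at least 1.25-fold to at least 7.4-fold. The highest belonged to a probe at a mean log2 level of 9.13 with curcumin and 6.18 with DMSO (limma, adjusted p = 0.022). The 2 falls were at least 1.29-fold and at least 1.33-fold.

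Probes for the same transcript stretch agreed closely. Over 683 pairs of distinct tested probes that overlap on the same strand, the log2 ratios correlated at 0.98 across probe pairs, and in all 57 pairs with both probes past the threshold the direction was the same, while in 27 only 1 probe passed. The 581 pairs with identical sequence correlated at 0.99. The share of changed probes rose with signal, from 4.02% in the dimmest of 3 equal groups of probes to 16.2% in the middle group and 21% in the brightest, while the median standard error was 0.10 in the first and 0.12 in the others. Direction differed with base composition. Probes of 35% GC content were higher in 5.51% and lower in 9.83% of cases, and probes of 41.7% GC or more were higher in 7.73% and lower in 4.5%.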

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

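The test that turned the signs of the pairs and the split of the GC test by pair, with its test of the mean over the dye swap, were chosen after the results had been seen, and so were the alternatives that take pair 3 from a single array and remove the GC trend.

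The deposited ratios of the pair 3 array with curcumin in Cy5 had a median of 0.125 on the log2 scale, far from the range of -0.022 to 0.001 of the other 3 arrays of that orientation. About 1 in 20 groups shows such a gap by chance, and 44 groups were examined. The pair 3 array with curcumin in Cy3 also had the highest median of its orientation, 0.194 against 0.036 to 0.098, so a high median was not particular to 1 array. The 2 dye orientations also gave different ratios (limma, adjusted p under 0.05) for 609 probes, 3.64% of those tested, and 122 of these were among the changed probes. The mean over a dye swap cancels a dye effect only if that effect has the same size on both arrays of a pair. Whether it had for these probes was not tested.

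The 2 arrays of pair 3 correlated at 0.69, less than those of any other pair, although they hold the same extracts, so no biological explanation applies to their difference. Dim Cy5 signal on the second array would spare bright probes. Over the brightest of 3 groups the arrays still correlated at only 0.69, against 0.82 to 0.90 in the other pairs, which argues against dim signal. The same array had the highest spike-in intercept, 0.696, and the lowest spike-in correlation, 0.959, and what set it apart stays open. With pair 3 taken from its other array alone, 2881 probes were called, and 2219 of the 2295 calls were kept.

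The share of changed probes in the dimmest group was 0.19 times that in the brightest. Whether dim probes lie below the reach of the test stays open, since that ratio only restates the pattern. The median standard error was 0.10 in the dimmest group against 0.12 in the brightest, which does not show an equal reach. The normexp offset of 50, added to every signal, shrinks both the ratios and their spread most in dim probes. How much it shrank them was not tested. Within each group by signal, the shares of changed probes in the highest and lowest GC groups differed by at most 1.15 times. Neither end of GC content thus held many more of the changes. A trend that raises GC-rich probes and lowers GC-poor ones could add calls at both ends. These shares therefore cannot exclude GC content as a source of calls.

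Direction followed GC content, with a positive slope of the curcumin over DMSO ratio in 7 of 8 arrays, which met neither outcome fixed in advance for a dye effect. A GC bias of the dyes would turn sign when the dyes are exchanged. In pairs 1 to 3 it did not: the lowest slope over their 6 arrays was 0.0803 per 10 percent GC, which argues against the dyes there. In pair 4 the slope was 0.109 with curcumin in Cy3 and -0.00916 ± 0.0077 (SE) with curcumin in Cy5; the mean over the dye swap kept a slope of 0.0498 ± 0.0069 (SE over probes, which are not independent), which argues against a dye effect of the same size on both arrays as the whole cause, while one that differs between the arrays stays open. With the trend removed from every array, 84.8% of the calls were kept in the same direction, so the trend alone did not set which probes were called. A bias of the extracts themselves, such as in RNA quality, was not tested, and neither was a biological explanation.

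For the 2295 changed probes, the signs of the 4 pairs can be turned in only 8 ways, too few for a share under 0.05: the real value was found in 1 of them and the highest of the others was 0. With the extracts unpaired, 1 of 35 splits of the 8 extracts, the real one, gave as many as its 255 probes, and the highest of the others was 0. The extracts are paired, however, and only 8 of these splits part all 4 pairs as the real one does, too few for a share under 0.05; the highest of the others among them was 0.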

How the results depend on the processing

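No call changed direction under any of the 25 alternatives, 5 of which were chosen after the data had been seen. For several this was fixed in advance. A change of threshold or variance model keeps the mean ratios. Leaving out 1 pair cannot turn calls that share a sign in every measured pair. The total count stayed within 1.5 times of 2295 in 17 of the 25, among them a replicate block on separate channels, where the pairs gave the same 2295 probes. That block restates the paired test, and the deposited ratios restate Agilent's processed signals, so neither adds a separate check. Unpaired, without that block, 255 were called, 130 higher and 125 lower. Leaving out 1 pair gave 0 to 2033 probes, 0 to 956 higher and 0 to 1077 lower, with fewer samples. Median centring gave 953, of them 85 higher, and its centre lay off the tested probes. Centring on these, an alternative chosen after the data had been seen, gave 2429. That centre draws rises and falls toward balance by construction, so it cannot tell a technical shift from an overall fall. Arrays with curcumin in Cy5 alone gave 1171, 449 higher and 722 lower; those with curcumin in Cy3 alone gave 1575 higher and 1487 lower; the cause was not tested. There, and with the GC trend removed (1187 higher, 1057 lower), rises outnumbered falls, unlike the 1023 and 1272 reported. The unpaired counts given above also held slightly more rises than falls. By construction, an adjusted p under 0.01 left 1 probe, 1 higher and 0 lower, and a 2-fold minimum left 297, 112 higher and 185 lower. Agilent's processed signals gave 1615 and kept 50.4% of the calls. Q2_P18655 lost its call in 2 alternatives, Q2_P07014 in 4, Q2_P12526 in 3 and Q2_P00621 in 6. With saturated probes left out, both risen probes have no value. Gene lists and gene counts were not run for want of gene names. Signal over background limits the reach: 24721 probes were too dim to test.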

Other observations

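The coiled-coil class, tested without the 15 most fallen probes, came from looking at the largest falls; the 12 composition and motif classes were fixed before any ratio was computed.

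Among those 12 classes, none was higher or lower than the other probes after adjustment over the classes (limma camera). Closest was the class whose open frame holds the calcium-binding loop of EF-hand proteins: 3 of its 6 tested probes, which have 5 distinct sequences, fell and 1 rose, the median log2 ratio was -0.75, and camera gave p = 0.043, adjusted p = 0.52, with p = 0.29 at an estimated correlation. Camera's preset p, not adjusted over the classes, was 0.051 to 0.081 in 5 alternatives and under 0.05 in 14. Among the latter it was 0.0091 without pair 4, and 0.011 without the filter on dim probes, where the median was only -0.12. Adjusted over the list alone, the counts were the same, 1 higher and 3 lower. A pair of these probes with identical sequence, thus 1 observation, and the open frame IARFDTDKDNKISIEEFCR, singled out after their values were seen, fell by 1.14 and 1.11 on the log2 scale (limma, adjusted p = 0.013 for both). Another, with the frame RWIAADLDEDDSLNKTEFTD, fell by 1.20 (limma, adjusted p = 0.037). The counts, the median and camera's preset p of this class take the identical probes as separate. They therefore give that sequence extra weight, and the class was not tested over distinct sequences alone.

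Of 5 probes with the catalytic loop of protein kinases, 2 rose, by 1.62 and 1.63 on the log2 scale (limma, adjusted p = 0.013 for both). They carry the same 60 bases, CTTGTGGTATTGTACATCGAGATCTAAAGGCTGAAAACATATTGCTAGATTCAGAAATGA, with the frame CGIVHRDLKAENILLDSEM, so they are 1 observation. The other 3 had log2 ratios of -0.08 to -0.49 and did not pass. Adjusted over the list alone, 2 of the 5 were higher and 1 was lower. Of 107 hydrophobic frames 10 rose and 10 fell, and of 48 acidic frames 0 rose and 5 fell. Of 22 frames rich in lysine and arginine 2 rose and 5 fell, of 46 rich in cysteine 4 rose and 8 fell, and of 83 rich in serine and threonine 7 rose and 4 fell. Fry, which asks whether a class moves one way from 0 and not whether it differs from other probes, gave adjusted p = 0.014 for the acidic class and 0.019 for the lysine and arginine class. Both classes had a median log2 ratio of -0.09, against -0.037 over all tested probes. Against the other probes, camera gave p = 0.14 and 0.29 at the preset and 0.17 and 0.33 at an estimated correlation. The start of a zinc finger was found in 44 probes, of which 2 rose and 4 fell. The nucleotide-binding P-loop was found in 15, of which 1 rose, and the DEAD box in 5, of which 0 changed. Of 691 probes with the polyadenylation hexamer 51 rose and 41 fell, and of 1904 with no open sense frame 149 rose and 168 fell.

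A class of open frames rich in charged residues, with hydrophobic ones in a heptad pattern as in coiled coils, was defined after looking at the most fallen probes. Leaving out the 15 most fallen took only 1 probe from its 34, and 2 from the 109 charged frames without heptads. A hypothesis is that transcripts of proteins with long coiled coils, such as those of contractile filaments, fell as a group. Without the 15 most fallen probes, 33 coiled-coil-like probes, with 30 distinct sequences, had a median log2 ratio of -0.23. Of these probes 7 were lower and 1 higher (12 lower and 4 higher adjusted over the list alone). For them camera gave p = 0.0048, but p = 0.086 at an estimated correlation. The same class read on the antisense strand gave p = 0.52 at the preset correlation, over 11 probes. Over the whole class of 34, which includes the probe left out above, p was 0.0023 at the preset and 0.082 at an estimated correlation. Arrays with curcumin in Cy3 alone gave a median of -0.15 and p = 0.052 at the preset correlation, and the other 18 alternatives computed kept the call at that preset. The median was -0.13 without the filter on dim probes, -0.16 with the GC trend removed and -0.45 with median centring. Charged frames without heptads were lower too, with a median of -0.17 over 107 probes (p = 0.009 at the preset and p = 0.16 at an estimated correlation), so a coiled coil and charge alone cannot be told apart. No gene name is attached to these probes, so whether they come from filament proteins may be asked only with an annotation.

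Of the probe pairs that match opposite strands of one sequence, 380 had both probes tested. Their log2 ratios correlated at 0.44 across probe pairs (permutation p = 1e-04, the smallest that 10000 permutations can give). Probe pairs are not independent replicates and come from the same extracts, so this p covers spread over probe pairs and not over worms. Overlapping partners share bases, and direction followed GC content. How much GC content added to this correlation was not tested. In 85% of the pairs the signs were the same, and in the 5 pairs with both probes past the threshold the direction was the same, while in 50 pairs only 1 probe passed. Copying of one strand's signal in full onto the other during labelling would make such pairs as alike as same-strand pairs. The same-strand correlation was higher by 0.54 (95% bootstrap interval 0.47 to 0.61, over probe pairs and not over worms). This difference argues against copying in full as the whole cause. Partial copying could leave a dimmer partner with a noisier ratio. The probe pairs were not matched for brightness, so partial copying stays open. Antisense transcripts that change with their partners, untested here, may be another source.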
